A study of Mus musculus with 4 samples.

How the data were processed

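Libraries were made from liver CD4 T cells of male C57Bl6/J mice on chow or on the FFC diet, 1 mRNA and 1 antibody library per diet, each from a pool of 5 mice. Per the labels' protocols, intrahepatic leukocytes were sorted, about 10000 cells were loaded per condition, and sequencing aimed at about 100000 reads per cell for mRNA and 25000 for antibodies. The values are whole-number UMI counts, deposited as filtered feature-barcode matrices that were made with Cell Ranger 8.0.1 (mRNA samples) and 9.0.0 (antibody samples), per the file headers. The submitters' processing notes name Cell Ranger 3.0, Seurat 3.1.1, R 4.1.0, GRCm39 and mm10 instead, with no role for each, so the build behind each matrix is not given in the sources used here. No coordinates are reported for that reason.

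The mRNA matrices list 33696 genes for 6772 chow and 7245 FFC barcodes. The antibody matrices list 32285 genes and 17 antibodies for 6772 and 7667 barcodes, of which 6756 and 7237 are also in the mRNA matrix, and 31950 gene identifiers are in both kinds of matrix. Gene symbols were taken from the matrices. Gene UMIs of the mRNA and the antibody matrix were close in number (56904157 and 57423501 in chow, 53978014 and 55167012 in FFC). The gene counts of the antibody matrix may thus largely recount the same reads, and are not read as independent of the mRNA matrix. The panel holds no isotype control and no hashtag that would mark an animal, so counts per animal were not made.

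Cells with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. The mitochondrial limit removed 611 chow and 136 FFC barcodes, and 97 and 4 had too few genes. Scrublet, run in scanpy 1.11.5, marked 2 chow cells and 1 FFC cell, under the 0.5% taken as a sign that a doublet caller has not worked, and no cell was removed as a doublet. The alternative with doublets kept is therefore identical to the values reported, and doublets remain in the data. Clusters were made in Seurat 5.3.0 (R 4.3.3) by anchor integration of both libraries with 2000 variable genes, 30 components and Louvain resolution 0.8. T cell receptor and immunoglobulin segments, mitochondrial and ribosomal genes were left out of the variable genes. A cluster was named, with the ending -like, from marker lists. The thresholds of the naming were set after the data were seen: at least 3 markers 1.5-fold higher, and a mean log2 fold of markers of at least 0.4. Lists within 0.1 of the best were separated by the number of their markers among the top 10 genes of the cluster, and a cluster with more markers of another list there, or of low depth with weak markers, was not named. Clusters that missed these rules stayed unnamed, and their shares are given. Clusters of B-like, dendritic-like and mixed myeloid cells were taken out before T cell values were computed.

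UMIs were summed over the T cells of a library, or over those of a class with at least 100 cells in both libraries, and compared as log2 ratios of UMIs scaled to the library's total (CPM) with exact 95% intervals from the conditional binomial distribution. Shares of cells have exact (Clopper-Pearson) 95% intervals. All intervals cover counting error only. Each diet has 1 library, cells are not replicates, and no p-value was computed. Genes named over all T cells are the 12 with the highest and the 12 with the lowest ratio among those at least 1.5-fold apart, with at least 50 UMIs in the library with more and 20 in the library with fewer. T cell receptor, immunoglobulin, mitochondrial, ribosomal-protein and haemoglobin genes and unnamed gene models were left out. In each list up to 4 members with the largest absolute ratio may be named, and in each class the 5 highest and 5 lowest genes. Other genes named (Foxp3 and Ifng in their lists, and Ccr7 within naive or central memory-like cells) were chosen after their values were seen. A list's median was taken over members with at least 20 UMIs, beside its percentile among 10000 random lists of the same size matched on expression in 20 bins, which describes these libraries and tests nothing. With classes weighted equally, a gene's share of UMIs was averaged over the 7 classes compared in each library and the ratio taken of these averages.

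For shares of cells with a UMI of a gene, each cell was thinned to 2000 UMIs and shallower cells were left out. The genes of these shares were chosen after the data were seen. Antibody counts were read as shares of all antibody UMIs, as mean UMIs per cell and as the centred log ratio per cell, and positive cells were called with a mixture of 2 Gaussians from scikit-learn 1.9.0. Positive shares are given only for antibodies whose components were at least 2 standard deviations apart with a threshold of at least 5 UMIs in both libraries, a criterion set after the data were seen. Results for 1 antibody and for some genes are not reported here, though counts and medians of gene lists include all listed members. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

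The ratios were tested on simulated counts of 16680 genes drawn from the summed T cells of both libraries. Counting error was the only spread in them, as the intervals assume, with none between cells, mice or batches. The figures that follow therefore check the computation and not the rate of false calls in these data. Of the 95% intervals, 95.6% held the simulated ratio. The rule of size found 45.1% of 71 genes changed 1.5-fold, 93.9% of 66 changed 2-fold and 93.7% of 63 changed 4-fold, and 0.42% of 13035 unchanged genes. Comparisons, filters, marker and gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Alternatives covered integration, cluster resolutions 0.5 and 1.2, a stricter cell filter (at least 500 genes and at most 5% mitochondrial UMIs), the scaling, the weighting of cells and classes, minimum UMI numbers, the gene counts of the antibody matrix, and the scaling, threshold and barcodes of the antibody values. Added after the data were seen were the removal of cells with the highest 5% of doublet scores, a pairing of Tfh-like and PD-1 high-like cells, counts of unnamed clusters with the NKT-like, Th1 effector memory-like or cytotoxic CD4-like cells, and a count of Treg-like cells without their shallower cluster.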

Results

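Liver CD4 T cells were profiled from male C57Bl6/J mice kept on chow and from mice kept on a diet that the labels call FFC, in a series whose title sets healthy animals against animals with steatohepatitis, a form of fatty liver with inflammation. The mice were 34 weeks old and had been on their diet for 24 weeks. Cells of 5 mice were pooled per diet, and CITE-seq, which reads mRNA and oligonucleotide-tagged antibodies from the same droplets, gave 1 mRNA library and 1 antibody library per diet. The chow mRNA library held 56904157 UMIs in 6772 barcodes (median 7708.5 per barcode) and the FFC mRNA library 53978014 UMIs in 7245 barcodes (median 6123). With 1 library per diet there was no replicate check and no test of a diet effect, and the intervals given are 95% intervals that cover counting error only. The labels also place the 2 diets in different batches, so diet and batch cannot be told apart in any value given here. After filtering, 6161 chow and 7109 FFC cells remained. Of these, 5873 and 6969 were kept as T cells.

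In percentage points, the make-up of the T cell pool differed most in the share of naive or central memory-like cells, which express the lymphoid homing gene Ccr7. They made up 42.8% of the chow T cells (2514 of 5873, exact interval 41.5 to 44.1%) and 9.64% of the FFC T cells (672 of 6969, 8.96 to 10.4%), a share 4.44-fold lower in the FFC library (interval of the ratio 4.11 to 4.80). NKT-like cells, marked by the innate-like transcription factor gene Zbtb16 and by NK receptor genes, were 12.3% (11.4 to 13.1%) of the chow and 2.90% (2.52 to 3.32%) of the FFC T cells, 4.24-fold lower (3.64 to 4.93). The Th1 effector memory-like, cytotoxic CD4-like and Tfh-like classes were larger shares of the FFC library. Th1 effector memory-like cells were 7.19% of the chow and 24.8% of the FFC T cells, 3.46-fold higher (3.13 to 3.82). Their cluster had a lower mean log2 fold of Th1 effector memory markers (0.50) than 2 unnamed clusters (0.84 and 1.39), and with these counted in the log2 ratio was 0.74 against 1.79. Cytotoxic CD4-like cells, led by Eomes and Gzmk, were 2.11% and 11.7%, 5.53-fold higher (4.59 to 6.65), and their log2 ratio was 1.84 against 2.47 with 1 of the unnamed clusters counted in. Tfh-like cells, led by Sostdc1 and Tnfsf8, were 4.65% and 15.5%, 3.33-fold higher (2.93 to 3.79).

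Regulatory (Treg-like) cells were 8.22% (7.53 to 8.96%) of the chow and 12.3% (11.6 to 13.1%) of the FFC T cells, 1.501-fold higher (1.35 to 1.67). They joined 2 clusters, and without the shallower one (median 1817 UMIs) the log2 ratio was 0.433 against 0.585. Th17-like cells were 1.26% and 2.97%, 2.36-fold higher (1.81 to 3.07), and interferon-response-like cells 0.63% and 1.78%, 2.82-fold higher (log2 ratio 1.498, interval 0.97 to 2.03). The interferon-response-like log2 ratio was 0.68 with the gene counts of the antibody matrix. Proliferating cells were 4.97% and 3.39%, 1.47-fold lower (1.24 to 1.74). Th2-like cells were rare in both libraries (46 and 67 cells), and the interval of their ratio (0.84 to 1.78) included equal shares. With the gene counts of the antibody matrix their log2 ratio was -0.10 against 0.30. The Tfh-like ratio depended on the clustering. At resolution 1.2 a cluster of 233 chow and 1051 FFC cells was named PD-1 high-like instead, and the log2 ratio of the 43 and 59 cells still named Tfh-like was 0.21 against 1.74. Counted with that cluster it was 1.76, a pairing chosen after the data were seen. The NKT-like log2 ratio of -2.08 ranged from -2.80 without integration to -1.49 without the cells of highest doublet score. The NKT-like shares moved as well, to 22.9% of the chow and 3.29% of the FFC T cells without integration. A cluster with Cd160, Xcl1 and Gzmb among its leading genes stayed unnamed, since its mean log2 fold of markers was 0.84 for both the NKT and the Th1 effector memory markers. It held 9.06% of the chow and 3.79% of the FFC T cells. Another unnamed cluster, led by Gzma, Zeb2 and Cx3cr1, had mean folds of 1.39 for the Th1 effector memory and 1.36 for the cytotoxic markers and held 1.40% and 0.90%. All 5 unnamed T cell clusters together held 15.1% and 14.0% (log2 ratio -0.11), but the log2 ratio of unnamed cells was 1.52 without integration, 1.45 with the stricter cell filter, 1.03 without the cells of highest doublet score and 0.59 with the gene counts of the antibody matrix. The cells had been enriched with CD4 beads and sorted as CD3+CD4+, so the NKT-like share is that of the sorted cells. B-like cells, which the sort should remove, were 3.88% of all kept chow cells and 1.03% of all kept FFC cells.

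**Figure D1:**
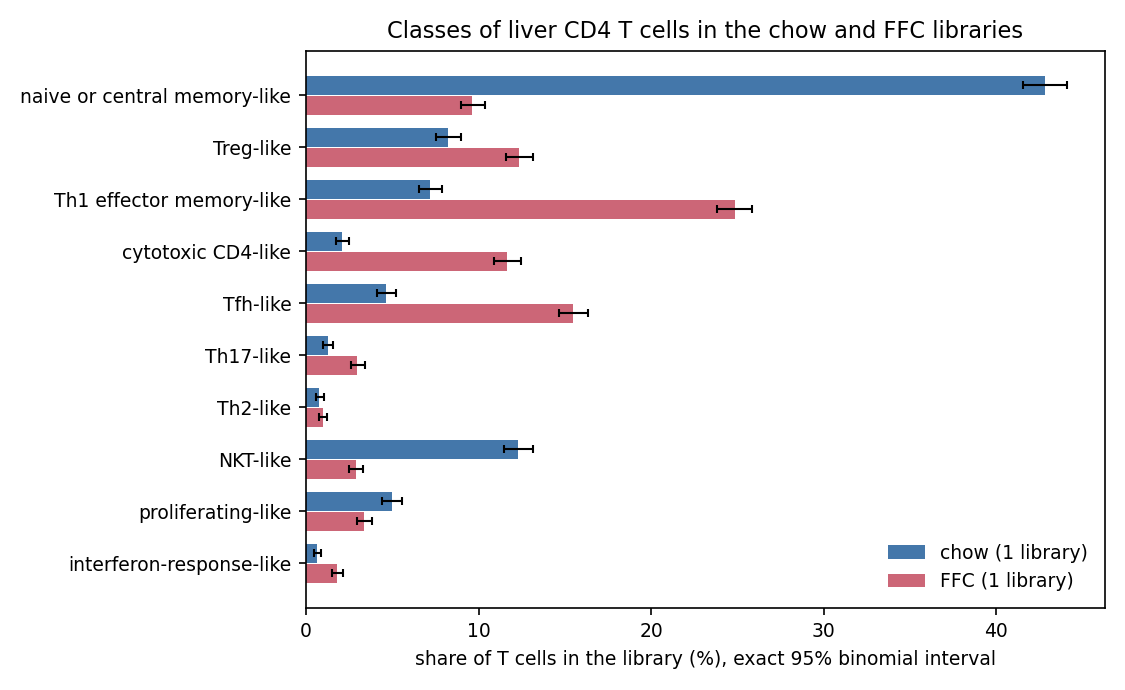
Share of T cells in each named class (horizontal axis, percent) in the chow library (blue) and the FFC library (red), with exact 95% binomial intervals that cover counting error only. Naive or central memory-like cells took 42.8% of the chow and 9.64% of the FFC T cells, while the Th1 effector memory-like share was 7.19% and 24.8%.

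Shares of cells with a UMI of single marker genes were compared after every cell was thinned to 2000 UMIs, because the T cells of the 2 libraries differed in depth (median 8064 UMIs for chow and 6148 for FFC). This left out 106 chow and 474 FFC T cells. B-like cells of the same libraries (median 7420 and 9759 UMIs) served as a reference that should lack most of these genes. They may hold T cell RNA, as no doublets were removed. A Cd4 UMI was seen in 11.4% and 17.1% of the thinned B-like cells, against 25.5% and 38.0% of T cells. A T cell share inside a B-like interval is thus unresolved, and not shown to be background. Ccr7 was seen in 24.0% of the thinned chow and 7.42% of the thinned FFC T cells (45.2% and 15.2% unthinned). Since B cells also express Ccr7 (39.7% and 20% of the thinned B-like cells), these give no background for it. Zbtb16 was seen in 9.78% and 1.12% (19.4% and 2.42% unthinned), against 0.84% and 0 of the thinned B-like cells. Because the FFC figure has only 70 thinned B-like cells behind it, its exact interval reached 5.13%, so the FFC level of Zbtb16 was not separable from that of the B-like cells. Gzmk, a granzyme gene, was seen in 3.14% and 16.4% (5.52% and 25.3% unthinned), against 1.69% and 1.43% of the B-like cells, and Eomes in 1.21% and 6.64% (2.66% and 11.95% unthinned), against 0.42% and 1.43%. The B-like intervals (0.46 to 4.27% and 0.036 to 7.70% for Gzmk, 0.011 to 2.33% and 0.036 to 7.70% for Eomes) included the chow values of both genes and the FFC value of Eomes, and only the FFC share of Gzmk was above its B-like interval. Pdcd1, which encodes the inhibitory receptor PD-1, was seen in 2.20% and 13.1% (6.21% and 26.8% unthinned), against 0.84% and 4.29%, and the thinned FFC share alone was above the B-like interval (0.10 to 3.02% and 0.89 to 12.02%). Unthinned, Pdcd1 was seen in 4.18% of the chow and 28.8% of the FFC B-like cells, which were deeper than the FFC T cells. Foxp3, the Treg lineage factor, was seen in 3.66% and 5.39% (7.83% and 10.7% unthinned), against 2.53% and 4.29% of the B-like cells. The B-like intervals for Foxp3 (0.935 to 5.43% and 0.89 to 12.02%) included both T cell values, so neither share was separated from the B-like cells. Unthinned, Foxp3 was seen in 7.95% and 21.9% of the B-like cells. Ifng was seen in 13.3% and 12.01% (27.1% in both unthinned), against 2.95% and 2.86%, and the log2 ratio of its thinned shares was -0.15 (interval -0.28 to -0.01).

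Summed over all T cells, the genes with the highest ratios in the FFC library included immune receptor, chemokine and granzyme genes. Cd8a (ENSMUSG00000053977), a chain of the CD8 co-receptor, was highest, with 61 UMIs in chow and 1005 in FFC (log2 ratio 4.07, interval 3.70 to 4.47). Of the FFC Cd8a UMIs, 69.4% lay in 1 unnamed cluster that held 3.19% of the FFC and 1.29% of the chow T cells and had Ccl3, Ccl4, Cd8b1, Havcr2 and Il10 among its other leading genes. Without integration a cluster with Cd8a and Cd8b1 in the lead held 3.02% and 0.26%. The CD8 list has 2 genes and so could not meet the naming rule of 3 markers. Pdcd1 (ENSMUSG00000026285) was 6.73-fold higher in the FFC library (log2 ratio 2.75, interval 2.63 to 2.87), the chemokine gene Ccl3 7.08-fold higher (log2 ratio 2.82, 2.66 to 2.99), the inhibitory receptor gene Lilrb4a 6.80-fold higher (2.77, 2.61 to 2.92) and Gzmk 6.29-fold higher (2.65, 2.56 to 2.75). The vitamin D receptor gene Vdr (log2 ratio 3.21), Prss2 (3.21), Coch (3.01), Grip2 (2.93), Bace2 (2.93), Krt83 (2.89) and Sh3rf2 (2.60) completed the 12 highest, each on fewer than 100 chow UMIs. With the 7 compared classes weighted equally in both libraries, Lilrb4a was at 2.17, Ccl3 at 2.02, Pdcd1 at 1.35 and Gzmk at 0.58. Prss2 (1.72) and Sh3rf2 (1.51) were also over 1.5-fold closer to 0, as were Vdr (1.67), Coch (1.63) and Bace2 (1.40). However, Vdr and Bace2 had enough UMIs to be measured in only 1 of the 7 classes and Coch in 2. The weighted values of Vdr, Bace2 and Coch are therefore not read as levels at equal class shares.

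The 12 lowest ratios were those of Htr1f (log2 ratio -3.80), Cdk8 (-3.06), Il4 (-2.77), Cd200r3 (-2.67), Zbtb16 (-2.66), Aff2 (-2.65), Plaur (-2.61), Or52ac1 (-2.58), Aqp9 (-2.56), Cmss1 (-2.50), Il1rapl1 (-2.50) and Gcnt2 (-2.50). Zbtb16 and the cytokine gene Il4, both typical of liver NKT cells, were 6.34-fold and 6.84-fold lower in the FFC library. With the classes weighted equally their log2 ratios were -1.06 and -1.79. Those of Plaur (-1.35), Aqp9 (-1.16) and Gcnt2 (-1.37) were also closer to 0, whereas Or52ac1, measured in 3 of the 7 classes, was at -3.92. Cd200r3 (-1.30) and Aff2 (-0.88) were closer to 0 too. However, Cd200r3 had enough UMIs to be measured in only 1 of the 7 classes and Aff2 in 0. The weighted values of Cd200r3 and Aff2 are therefore not read as levels at equal class shares. Cdk8 (ENSMUSG00000029635) and Cmss1 (ENSMUSG00000022748) were by far the most abundant of the 12 (57075 and 206673 chow UMIs). They were lower in all 7 compared classes, by log2 ratios from -3.31 to -2.54 for Cdk8 and from -2.72 to -2.01 for Cmss1. In the B-like cells, which are not part of the T cell pool, the log2 ratio of Cmss1 was -2.32 and that of Cdk8 -2.36.

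**Figure D2:**
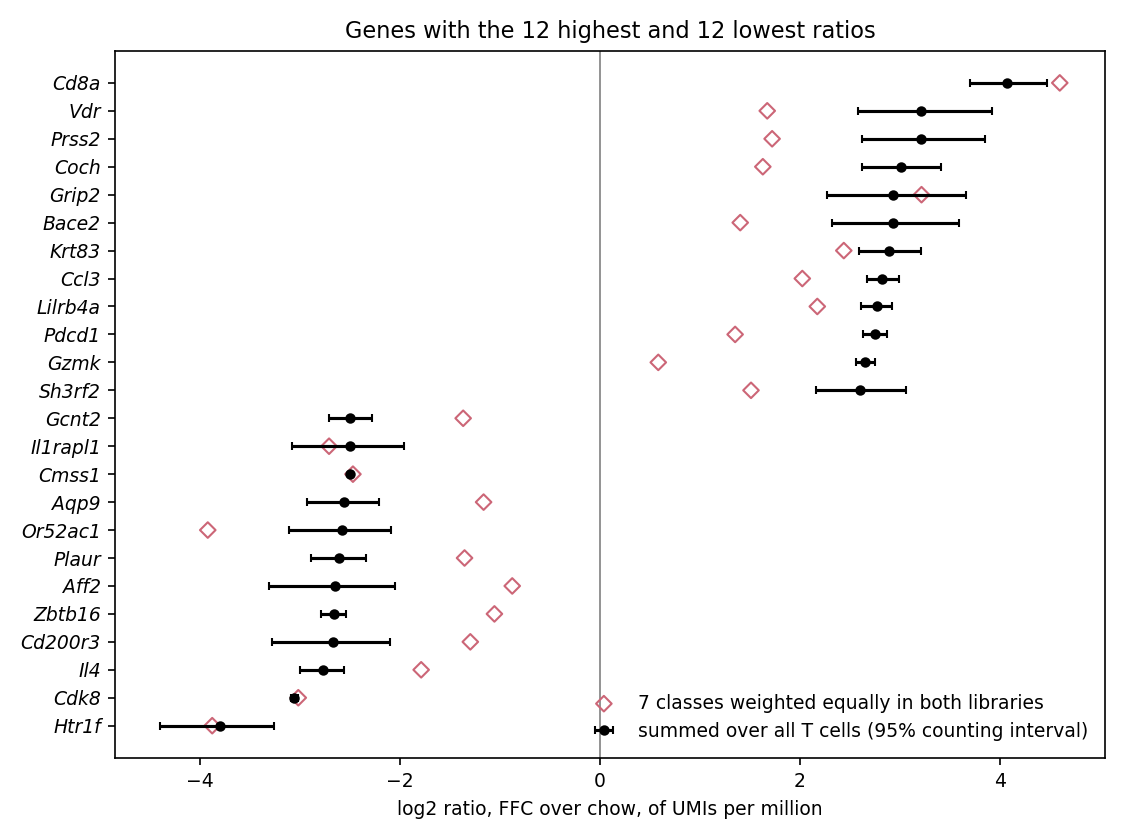
Log2 ratio, FFC over chow, of scaled UMI counts (CPM, horizontal axis) for the 12 genes with the highest and the 12 with the lowest ratio over all T cells. Black points are sums over all T cells with 95% counting intervals and red diamonds the ratio with 7 classes weighted equally, which lay at 0.58 for Gzmk against 2.65 unweighted.

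Gene groups fixed in advance were compared by the median log2 ratio of their members over all T cells, beside 10000 random lists matched on expression. The scaling to CPM left the median gene with at least 100 UMIs at a log2 ratio of 0.14. Members are called higher or lower where they differed by at least 1.5-fold. Among 12 naive and recirculation genes, 8 were lower and 0 higher in the FFC library (median -1.01, percentile 0), among them Igfbp4 (-1.82), Ccr7 (-1.71) and the chromatin organiser gene Satb1 (-1.51). Among 12 NKT genes, 7 were lower and 1 higher (median -1.08, percentile 0), with the NK receptor gene Klrb1c at -2.32 and Cd160 at -2.22. Among 13 inhibitory receptor and exhaustion genes, 7 were higher and 1 lower (median 0.90, percentile 100). Pdcd1 led, followed by Havcr2 (1.66), which encodes TIM-3, and Tigit (1.33), while Cd160 was the lower one. Among 10 Tfh genes, 6 were higher and 0 lower (median 0.83, percentile 100), including the cytokine gene Il21 (1.496). Among 16 Treg genes, 10 were higher and 1 lower (median 0.95, percentile 100). The members that led were the costimulatory receptor gene Tnfrsf4 (1.98), Areg (1.89), Nrp1 (1.66) and Il10 (1.59), genes that other activated T cells also express, whereas Foxp3 was at 0.38. Over 6 alternatives, log2 ratios shrank to as little as -0.11 for Igfbp4, -0.66 for Ccr7, -0.19 for Satb1, -0.73 for Klrb1c and -1.05 for Cd160. Those of higher genes shrank to 0.23 for Havcr2, 0.32 for Tigit, 0.38 for Il21, 1.15 for Tnfrsf4, 1.24 for Areg, 0.64 for Nrp1 and 0.49 for Il10.

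Among 19 cytokine and chemokine genes, 11 were higher and 2 lower (median 1.11, percentile 100). Il17a (1.962), Tnfsf11 (1.84), which encodes RANKL, and Ccl3 were higher, and Il4 was lower. Among 13 Th1 genes, 6 were higher and 1 lower (median 0.49, percentile 99.97), with Hopx at 1.45 and Ccl5 at 1.248 but the interleukin-12 receptor gene Il12rb2 at -0.99 and Ifng at -0.32. Among 12 cytotoxic effector genes, 3 were higher and 1 lower (median 0.32, percentile 98.0), as Gzmk (2.65) and Eomes (1.89) differed in direction from Gzma (-1.65). With classes weighted equally Eomes was at -0.10. Among 18 interferon response genes, 8 were higher and 0 lower (median 0.48, percentile 99.99), including Ifit3 (1.73) and Isg15 (1.23). Among 16 residency and liver homing genes, 9 were higher and 2 lower (median 0.63, percentile 100), with the integrin genes Itgb1 (1.23) and Itga4 (1.12) opposite in direction to Itga1 (-0.95). Th17 genes had a median of 0.48 (4 of 11 higher, 1 lower, percentile 99.77) and costimulatory receptor genes 0.37 (4 of 10 higher, 0 lower, percentile 99.64). Among 16 cholesterol and lipid synthesis genes, 5 were lower and 0 higher (median -0.38, percentile 0), including Sqle (-0.87) and Fdps (-0.86). Fatty acid oxidation genes had a median of 0.30 (3 of 14 higher, percentile 97.54), with the carnitine transferase gene Cpt1a at 1.06, and lipid uptake and efflux genes one of 0.37 (2 of 10 higher, percentile 97.64). Glycolysis genes had a median of 0.34 (1 of 14 higher, percentile 99.56) and proliferation genes one of -0.06 (0 of 13 higher or lower, percentile 0.16). Inside the 95% range of the random lists were the medians for TGF-beta signalling (0.22), T cell receptor activation (0.22), S100 and migration (0.20) and heat shock and dissociation stress (0.17). Oxidative phosphorylation (0.07) and Th2 genes (0.12) changed sign, to -0.07 and -0.02, once the shift was taken off. Over 6 alternatives, single log2 ratios shrank to as little as 0.14 for Il17a, 0.93 for Tnfsf11, 0.33 for Ccl5 and -0.21 for Il12rb2. Those of Itgb1 and Itga4 shrank to 0.37, that of Itga1 to -0.23 and that of Ifit3 to 1.05.

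Weighting the classes also left out the Th17-like, Th2-like, interferon-response-like and unnamed cells, so the moves that follow are not put down to class shares alone. With the 7 compared classes weighted equally in both libraries, the medians of the inhibitory receptor (-0.09), Tfh (-0.13), Th17 (-0.10), T cell receptor activation (-0.03), S100 and migration (-0.21) and Th2 (-0.49) groups turned negative and those of the NKT genes (0.31) and the proliferation genes (0.01) turned positive. The naive and recirculation median shrank to -0.20 and the cytokine and chemokine median to 0.38. The Treg (0.56), Th1 (0.24), residency and liver homing (0.17), fatty acid oxidation (0.17), costimulatory receptor (0.10), glycolysis (0.10) and cytotoxic effector (0.08) medians shrank too. The cholesterol and lipid synthesis (-0.47), interferon response (0.36) and lipid uptake and efflux (0.40) medians moved less.

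**Figure D3:**
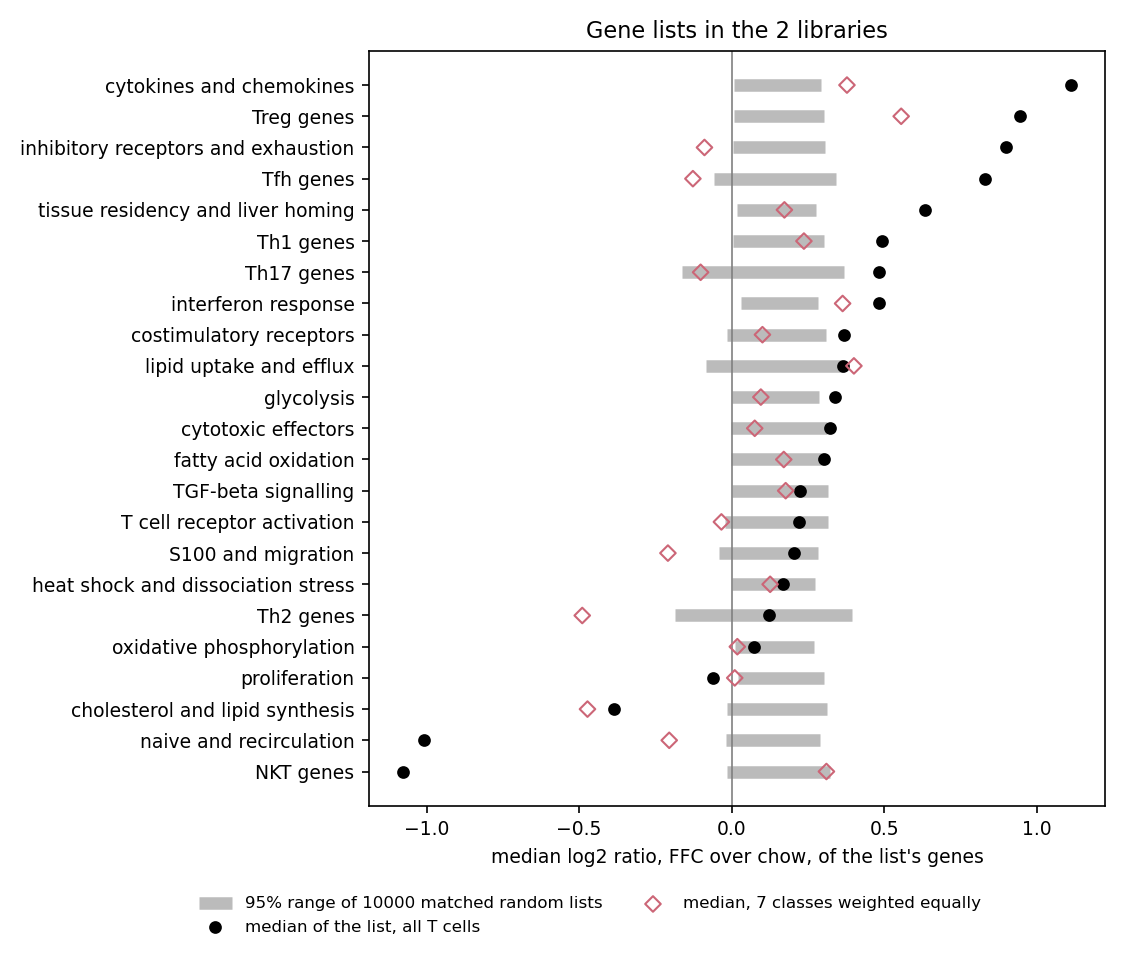
Median log2 ratio, FFC over chow, of each gene group (horizontal axis). Black points are medians over all T cells, red diamonds medians with 7 classes weighted equally, and grey bars the 95% range of 10000 matched random lists. The inhibitory receptor median was 0.90 over all T cells and -0.09 with classes weighted equally.

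Within classes, sums over the cells of one class were compared in the 7 classes with at least 100 cells in both libraries. Cdk8 was among the 5 lowest genes in all 7. In Treg-like cells the 5 highest were Asb2 (log2 ratio 2.82), Gzmk (2.65), Evi5 (2.64), Epcam (2.60) and Tnfsf11 (2.55), and the lowest included the gut homing receptor gene Gpr15 (-2.75) and the mitotic genes Ube2c (-2.74) and Cdca3 (-2.43). Treg-like cells were also much shallower in the FFC library (median 4349 UMIs against 7930 in chow), and the shallower of their 2 clusters held 48 of 483 chow but 163 of 860 FFC cells. In Th1 effector memory-like cells Gzmk (2.68), the TGF-beta target gene Pmepa1 (1.97) and Lilrb4a (1.80) were among the highest and Klrb1c (-3.51) was the lowest. Klrb1c rested on 83 chow and 26 FFC UMIs. NKT genes had a median of -2.26 in this class and proliferation genes one of -0.67. Whether the make-up of the class differed between the libraries was not tested. In cytotoxic CD4-like cells Coro2a (1.76) and Pmepa1 (1.45) were highest, and Slit3 (-4.04) and Ptprk (-3.30) lowest. In Tfh-like cells Tmem163 (1.94) and Cish (1.62), a cytokine-induced inhibitor of signalling, were highest. In naive or central memory-like cells the highest were Nrp1, followed by Bhlhe40 (1.84), Slc15a2 (1.62), Cxcr3 (1.57) and Itgb1 (1.499), while Ccr7 was at -0.03. In proliferating cells Ccl3 (3.97), Gzmk (3.74), Ccl4 (3.05) and Lilrb4a (3.03) were highest. The 2 CD8 genes, markers of another cell type, had a median of 3.68 in the same class. In NKT-like cells the interferon-induced genes Ifitm2 (4.55) and Ifitm3 (2.94), Klra5 (3.84), Tnfrsf4 (3.59) and Gzmc (3.49) were highest and Il4 (-2.05) among the lowest. The NKT-like class came from 2 clusters, whose sizes were 530 and 191 cells in chow and 104 and 98 in FFC, so the balance between them also differed. With the gene counts of the antibody matrix some of these log2 ratios were over 1.5-fold away: Slit3 was at -1.30, Asb2 at 2.06, Klrb1c at -4.24, Ifitm2 at 3.74, Ifitm3 at 2.31, Gzmc at 2.78 and Il4 at -2.64.

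Markers of other cell types were followed in the same libraries. The share of B-like cells among all kept cells was 3.78-fold lower in the FFC library (2.91 to 4.90). Dendritic-like cells were 0.44% and 0.14%, and a mixed myeloid and dendritic cluster 0.36% and 0.80%. Among the retained T cells, the B cell list had a median log2 ratio of -0.57 (0 of 6 higher, 3 lower), the hepatocyte list -1.17 (1 of 6 higher, 4 lower; Alb at 126 and 10 UMIs), the myeloid list 0.49 (1 of 4 higher, 1 lower) and the endothelial list -0.02 (0 of 4 higher or lower). With classes weighted equally the B cell median was -1.18, and with a minimum of 100 UMIs the hepatocyte median was -1.91. The 2 CD8 genes had a median of 2.99, with Cd8b1 at 1.92. Mitochondrial transcripts made up 3.25% of the T cell UMIs in chow and 1.74% in FFC, and 611 chow against 136 FFC barcodes exceeded the limit of 10% mitochondrial UMIs.

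Surface proteins are given for 16 antibodies, read in 5858 chow and 6963 FFC T cells. Cells of the chow library carried more antibody UMIs (median 1827 per T cell, against 892 in FFC), and CD44, an activation and memory marker, alone took 56.0% of the antibody UMIs in chow and 78.8% in FFC. By share of antibody UMIs 15 of the 16 proteins were lower in the FFC library, by mean UMIs per cell all 16 were, and by median centred log ratio (CLR) 8 were. Shares and means differ by the same factor for every protein, so they do not support each other. The direction of CD44 depended on the scaling, since its log2 ratio was 0.49 by share and -0.68 by mean UMIs per cell, and its median CLR was 1.14 higher. NRP1, a receptor found on Treg and Tfh cells here, had a log2 ratio of -0.07 by share but a median CLR 0.78 higher in FFC.

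Median CLR was lower in FFC for CXCR4 (-0.39), CX3CR1 (-0.34), CCR7 (-0.30), CCR4 (-0.28), CCR6 (-0.25) and CXCR3 (-0.21). It was lower by less than 0.05 for CD25 (-0.01) and CD69 (-0.04). All 8 were among the 15 of 16 proteins lower by share. CX3CR1, CCR7 and CCR4 had a median of 1 UMI per FFC T cell (12, 9 and 9 in chow), so their CLR lies near the floor. CCR7 CLR and Ccr7 mRNA had a Spearman rho of 0.13 in chow and 0.0047 in FFC. Median UMIs per chow T cell were above those of the chow B-like cells for CD44 (955.5 against 555), CD127 (75 against 20.5) and CXCR4 (109 against 52.5) only, and in FFC for CD127 and CXCR4 only. For the others a share or CLR over all T cells is not read as expression, nor as its absence, since B-like cells may carry some of these proteins too. A mixture threshold separated positive from negative cells in both libraries for 4 of the 16 proteins (CD69, CD127, CD103 and integrin beta 7). The thresholds differed between the libraries, most for integrin beta 7 (183 UMIs in chow and 22.3 in FFC). Cells called positive thus need not be of the same kind in both. CD69-positive cells were 27.996% and 27.546%, and CD127-positive cells 77.1% and 74.3%. With 1 threshold for both libraries they were 28.7% and 9.36% for CD69 (log2 ratio -1.61 against -0.02), and 86.4% and 64.6% for CD127 (-0.42 against -0.05). CD103-positive cells were 8.62% and 11.7% and integrin beta 7-positive cells 9.30% and 26.9%, but with that threshold these 2 log2 ratios changed sign, from 0.44 to -0.14 and from 1.53 to -0.65. The shared threshold is a UMI count that was not adjusted for the fewer antibody UMIs of FFC cells, so its values carry that difference.

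Between classes of one library some antibodies followed the mRNA classes. Median CLR of CD44 was 1.81 lower in naive or central memory-like cells than in the other chow T cells and 1.68 lower in FFC. Integrin beta 7 was 2.11 and 1.53 higher in Treg-like cells. CD103, an integrin chain that many tissue Treg cells carry, was 1.73 and 1.30 higher in Treg-like cells. CD69, which marks recently activated and tissue-resident cells, was 2.44 and 0.98 higher in NKT-like cells, CCR6 0.74 and 1.07 higher in Th17-like cells, and NRP1 1.16 and 0.79 higher in Tfh-like cells. Differences were small for CXCR5 in Tfh-like cells (0.08 and 0.07) and for CD25 in chow Treg-like cells (0.06, against 0.37 in FFC). Across cells of a library, protein CLR and mRNA of the same gene had a Spearman rho of 0.63 (chow) and 0.58 (FFC) for CD127 and Il7r, 0.45 and 0.49 for NRP1 and Nrp1, and 0.58 and 0.32 for CD44 and Cd44. For CD69, CXCR4, CCR4, CXCR5 and CCR8 it lay between -0.02 and 0.04 in both libraries.

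**Figure D4:**
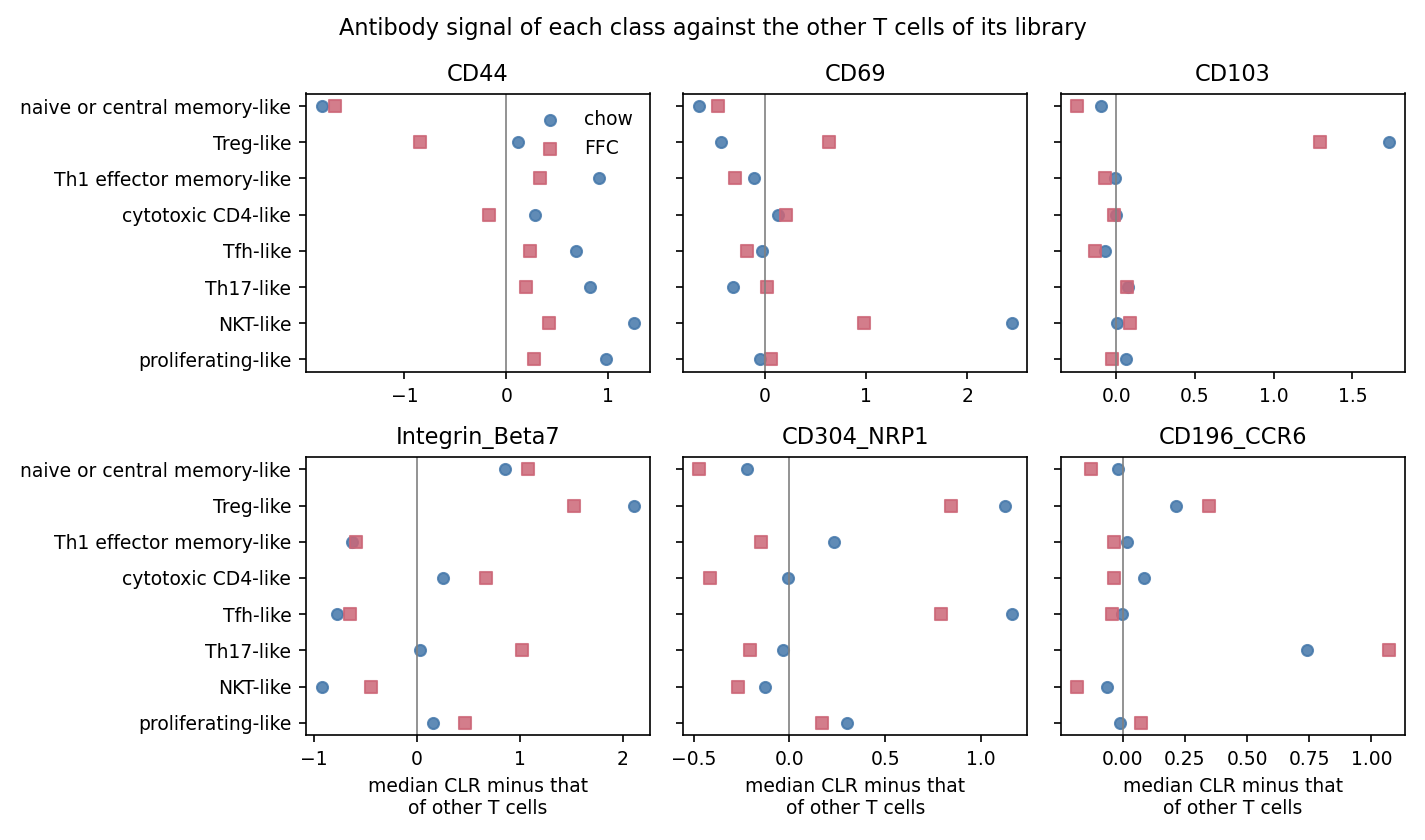
Median centred log ratio (CLR) of 6 antibodies in each class minus that of the other T cells of the same library (horizontal axis), for the chow library (circles) and the FFC library (squares). CD44 stood 1.81 and 1.68 lower in naive or central memory-like cells, and CD103 1.73 and 1.30 higher in Treg-like cells.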

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

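The tests of free RNA inside the Cd8a cluster, of doublets and CD4-negative cells, of the annotation, and of all explanations for the naive-like and NKT-like shares were chosen only after the result was seen.

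In data outside the comparisons, 5.61% of the FFC barcodes of the antibody matrix (430 of 7667) were absent from the FFC mRNA matrix, against 0.24% (16 of 6772) in chow. They had a median of 2571 gene UMIs, against 6145 for the other FFC barcodes. Trav11, the gene segment of the invariant NKT cell receptor and left out of the gene ratios, had a UMI in 8.74% of the chow NKT-like cells (63 of 721, exact interval 6.78 to 11.04%) and in 6.44% of the FFC NKT-like cells (13 of 202, 3.47 to 10.8%). Among B-like cells it was seen in 1 of 239 and 0 of 73. Cells without a Trav11 UMI are not shown to lack the segment, so these are not shares of invariant NKT cells. Gm42418, a gene that overlaps ribosomal RNA sequence and is present only in the antibody matrix, had a log2 ratio of -1.17.

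Cdk8 and Cmss1 were lower in the FFC library in all 7 classes compared, as were Lars2 (-0.97 over all T cells) and Camk1d (-0.98). A response of the T cells alone is argued against by the B-like cells, in which the log2 ratio of Cmss1 was -2.32 (interval -2.44 to -2.20). The annotation of 1 matrix is argued against by the antibody matrix, made with another Cell Ranger version, where the ratio in T cells was -2.47. Reads like ribosomal RNA counted to these genes stay open. Across cells the joint share of Cdk8 and Cmss1 rose with that of Gm42418 with a rho of 0.80 in chow and 0.36 in FFC. With Camk1d, itself lower, rho was 0.46 and 0.25, with Malat1 0.097 and -0.0019, and with Actb 0.032 and -0.076. However, AY036118 and Gm26917, other genes like Gm42418, had log2 ratios of only -0.23 and 0.06. A diet effect on all cells, a batch and such reads cannot be told apart here.

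Cd8a was higher in the FFC library, mostly in cluster 12. Free RNA is argued against inside that cluster, where Cd8a was at 319 CPM in FFC and at 10.7 CPM in B-like cells. The cluster was singled out for its Cd8a UMIs, which favours this outcome. Outside it Cd8a was at 6.23 CPM in T cells, and free RNA cannot be told apart from expression there, because the B-like value rests on 9 UMIs in 3 cells. Doublets of a CD4 and a CD8 cell may contribute, as Cd8a-positive cells of cluster 12 had 1.38 times the median UMIs of the other FFC T cells, between the bounds set for and against. Deeper cells more often show a Cd8a UMI, so part of this excess may come from how the cells were picked. Their median was 8426 UMIs, against 7916.5 for all FFC cells of cluster 12. CD8 cells without CD4 that passed the sort also stay open. At fixed depth a Cd4 UMI was 0.67 times as frequent (0.47 to 0.95) in the 90 cells of cluster 12 that kept a Cd8a UMI as in the other FFC T cells.

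Naive-like and NKT-like shares were lower in the FFC library. Lower depth is argued against for the naive-like part by the thinned share of T cells with a Ccr7 UMI (log2 ratio -1.70). For the NKT-like part it is argued against by the thinned share with a Zbtb16 UMI (log2 ratio -3.12). More blood left in the chow livers stays open for the naive-like part. B-like cells, frequent in blood, were also a smaller share (log2 ratio -1.92). Because the sort should remove them, their share may reflect the sort and cannot decide this. For the NKT-like part the log2 ratio with the naive-like cells taken off was -2.74. This could not test naive-like blood cells as a cause, because more of them in chow would make the chow NKT-like share smaller. Blood that brought NKT-like cells stays open. The number of batches that hold both diets was 0, so batch and diet cannot be told apart.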

How the results depend on the processing

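The tests that leave out the highest doublet scores, pair Tfh-like with PD-1 high-like cells, add cluster 5 to the NKT-like cells, add unnamed clusters to the Th1 effector memory-like or cytotoxic CD4-like cells or take cluster 15 from the Treg-like cells were chosen only after the result was seen. Of the alternative values, 64 of 65 of the 10 class share ratios kept their direction, as did 725 of 743 of single gene ratios, 70 of 70 within classes with the gene counts of the antibody matrix, 210 of 223 of list medians, 12 of 14 of marker shares, 40 of 48 of antibody shares and 2 of 4 of antibody-positive shares. Outside the reported counting interval lay 17, 236, 9, 57, 9, 47 and 4 of them, in the same order. Since the gene counts of the antibody matrix may largely recount the same reads, the 70 of 70 were nearly fixed in advance. The share of unnamed cells changed direction in 4 of 6 settings, to 1.52 at most. Unless the construction shows it, the cause was not tested for any value that follows, and all are log2 ratios unless named otherwise.

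Without integration the share ratio was 2.09 for cytotoxic CD4-like, 2.19 for Tfh-like, 1.66 for Th17-like, -2.80 for NKT-like, -0.82 for proliferating and 0.80 for interferon-response-like cells. Counting clusters 5 and 17 gave 0.74 for Th1 effector memory-like cells, and counting cluster 17 gave 1.84 for cytotoxic CD4-like cells. Resolution 0.5 gave 2.11 for cytotoxic CD4-like cells, and resolution 1.2 gave 0.21 for Tfh-like and 0.74 for interferon-response-like cells. The stricter cell filter gave 1.501 for Th1 effector memory-like and -1.62 for NKT-like cells, and 0.90 for the Tfh list. The gene counts of the antibody matrix gave -1.51 for NKT-like, 0.68 for interferon-response-like and -0.10 for Th2-like cells, whose reported interval included 0. NKT-like cells were at -1.49 without the highest doublet scores and at -1.67 with cluster 5, and Il13 was at 0.33 without the highest doublet scores.

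With 7 classes weighted equally, which removes differences in their shares and also leaves out all other T cells, list medians were -0.20 (naive and recirculation), 0.56 (Treg), 0.38 (cytokines and chemokines), -0.10 (Th17), -0.13 (Tfh), -0.089 (inhibitory receptors), -0.033 (T cell receptor activation), 0.010 (proliferation), -0.21 (S100 and migration), -0.49 (Th2) and 0.31 (NKT). Single genes that changed sign there were Maf (-0.086), Ascl2 (-0.48), Tox2 (-0.15), Eomes (-0.10), Apoe (-0.39), Jun (0.14), S100a4 (-0.28), S100a11 (-0.16), Klra9 (0.36), Cd68 (-0.38) and Dnase1l3 (-1.56). Values whose reported interval included 0 changed sign too: Stab2 to 0.99 and Fcgr2b to -0.84 with this weighting, and Fcgr2b also in 4 other settings. The Th2 median turned to -0.02 with the median ratio set to 0 and to -0.095 with no minimum of UMIs, and the endothelial median to 0.03 in 2 settings. As means over cells, the medians were -0.96 (naive and recirculation), 0.83 (cytokines and chemokines) and -1.74 (NKT). With the median ratio set to 0 they were -1.15 (naive and recirculation), 0.80 (Treg), 0.76 (inhibitory receptors) and -0.069 (oxidative phosphorylation).

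Thinning to fixed depth, which removes the depth difference, turned the share of cells with a Cxcr6 UMI to -0.13 and that with an Ifng UMI to -0.15. Mean antibody UMIs per cell, which carry the lower antibody total of the FFC library, gave -0.68 for CD44, and all barcodes of the antibody matrix 0.54. The difference in median CLR was 1.14 for CD44, 0.17 for TIM-3, 0.30 for CD127, 0.16 for CD103, 0.20 for integrin beta 7, 0.78 for NRP1, 0.052 for CXCR5 and 0.11 for CCR8. With 1 threshold for both libraries, which also carries the lower antibody total of FFC, the positive share was at -0.14 for CD103 and -0.65 for integrin beta 7. For CD69 it was at -1.61 against -0.02. No paired analysis was possible because each diet has 1 library per kind.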

Other observations

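The comparison of gene groups within classes that follows was planned, but the groups named here and the tests of Trav11 outside NKT-like cells were chosen only after the result was seen.

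Within classes, cholesterol and lipid synthesis genes had a lower median in the FFC library in Treg-like (log2 ratio -0.77), proliferating (-0.66), Tfh-like (-0.50), Th1 effector memory-like (-0.49) and NKT-like cells (-0.38), but not in naive or central memory-like (0.24) or cytotoxic CD4-like cells (0.00). Interferon response genes had medians from 0.17 in Th1 effector memory-like to 0.54 in cytotoxic CD4-like cells. In Th1 effector memory-like (percentile 92.8) and Treg-like cells (0.27, percentile 89.3) these lay inside the 95% range of matched random lists, and in the other 5 classes above it. S100 and migration genes had a median of -0.92 in Treg-like and -0.38 in proliferating cells, but of 0.77 in NKT-like and 0.30 in Tfh-like cells. In Treg-like cells naive and recirculation genes had one of -0.87, while cytokine and chemokine genes had one of 0.89. Heat shock and dissociation stress genes had a median of 0.45 in the same class (7 of 16 higher, 0 lower). NKT genes had a median of -2.26 in Th1 effector memory-like cells and of 0.40 in NKT-like cells. In Tfh-like cells the median of the cytotoxic effectors was 1.04. Depth differed most in the Treg-like class (median 7930 UMIs in chow and 4349 in FFC).

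Trav11 had a UMI in 18 of 532 cells (3.38%) of the unnamed cluster with Cd160 and Xcl1 in chow and in 0 of 264 in FFC, whose exact interval reached 1.39%. In the other T cells it was seen in 9 of 4620 chow cells and 1 of 6503 FFC cells.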
